A study of Homo sapiens with 2 samples.

How the data were processed

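RNA from HEK 293T cells with an induced eGFP vector and from cells with an induced eGFP-hTLX vector was sequenced as 2 libraries, 1 per group. Per the labels' protocols the libraries were strand-specific and depleted of ribosomal RNA, with paired reads of 125 bases. The values are FPKM per gene as the authors deposited them, that is, fragments per kilobase of transcript, scaled to sequencing depth. FastQC 0.11.5, Trim Galore 0.3.3, HTSeq 0.6.1, Cufflinks 2.2.1 and the build hg19 are named per the submitters' processing notes, which give no role or order. The aligner and the annotation are not given in the sources used here. Read counts, estimate status and confidence intervals were not used here.

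Each file listed 63176 rows for 63000 identifiers. For the 120 identifiers with several rows, the row with the highest mean was kept. Of the identifiers, 51904 (82.4%) were found in GENCODE 29 on GRCh38 and took their position, type, transcript length and GC content from it. The files hold no coordinates, so all coordinates are those of GRCh38 and none were converted from hg19. Gene symbols are those of the files, and 3 distinct list symbols (TIGAR, CXCL8 and NORAD) had no match.

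Depth was estimated from the smallest steps of the FPKM values. Genes with a single annotated transcript of at least 1500 bases and FPKM times length in kb between 0.024 and 0.034 were taken to hold 1 fragment, which was 109 genes in the eGFP library and 176 in the TLX library. The depth ratio of 1.08 is the median over 15 genes at 1 fragment in both libraries, with quartiles of 1.08 and 1.09. Fragments behind a value were approximated from the median annotated transcript length, and the 95% intervals of ratios come from these counts, so they cover counting error only and say nothing of the spread between cultures.

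Differences are log2(FPKM + 1) of the TLX library minus that of the eGFP library, for genes with at least 1 FPKM in at least 1 library. A difference of at least 1 is called 2-fold. No test was run, because 1 library per group gives no spread. For each gene list, the median difference of its members past the filter was placed among 10000 random lists of the same size matched on mean expression in 20 bins, over 14312 symbols. A list stood apart below percentile 2.5 or above 97.5, and a list with fewer than 5 such members was given as values only.

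The named genes are NR2E1, the 10 largest increases and 10 largest decreases among genes with at least 5 FPKM in at least 1 library and a symbol that is not a clone name, a small RNA name or letters and digits followed by P and a number (a pattern that the pseudogene names RMRPP4 and SFTA1P do not match), up to 4 members of each list with the largest differences, and all measured members of the lists on the NR2 family, TLX partners and reported TLX genes. Where the text summarises a list, fewer members are named, and some genes are not reported here, although list medians and counts include them. The groups, this rule, the 50 gene lists, the 2-fold measure and most alternatives were fixed before the data were examined. The ranking of 15 genes each way, the reference genes, the chromosomal regions, the zinc finger cluster, 5 second gene lists and 4 alternatives were chosen after the data were seen.

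The alternatives were pseudocounts of 0.1 and 5, no low-value filter and a filter of 5 FPKM, and thresholds of 1.5-fold and 4-fold. They also included rescaling to the same sum, centring on the median, rescaling to the same upper quartile, leaving out mitochondrial, small and short RNA before rescaling, list means, and 50 bins. Short RNA were genes whose longest GENCODE 29 transcript is under 300 bases, in place of the planned locus under 300 bases. Added later were genes above 0 in both libraries, protein-coding genes only, leaving out distal 18q and chromosomes 9 and 20, and random lists matched on GC content and length too, in 8 bins of expression, 5 of GC content and 5 of length.

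The calculation was tested on simulated data for this comparison with 14335 genes and noise of SD 0.2 in log2. Changes were placed only in genes with a mean of at least 5 FPKM, 50 per size, so the rates for changed genes do not cover lower genes. It called 2% of genes simulated at 1.5-fold, 98% at 3-fold, 100% at 4-fold and 100% at 8-fold, and 0% of unchanged genes. Noise was drawn gene by gene, so the simulated lists held no members that vary together. Among 42 simulated lists without a shift, 2.38% stood apart, and 100% of lists shifted by 0.3 did. Real noise between cultures is unknown. The observed differences had an SD of 0.74 over all genes. Over 3793 protein-coding genes with a mean level of at least 20 FPKM it was 0.36. The simulated rates may therefore not hold for these libraries. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.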

Results

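The data were gene expression values from 2 RNA sequencing libraries of HEK 293T cells, a human embryonic kidney line that is widely used for transfection. One library came from cells carrying an induced eGFP vector and the other from cells carrying an induced vector for eGFP with human TLX. TLX is an orphan nuclear receptor of neural stem cells, encoded by NR2E1, that mostly acts as a transcriptional repressor. The comparison asked how the transcriptome of the cells with TLX differed from that of the cells with eGFP alone. Each group had 1 library, so no difference below has a replicate check, no p-value is given, and every statement describes these 2 libraries. FPKM values summed to 1274500 in the eGFP library and 1124880 in the TLX library, with 62.2% and 59.4% of the sums in small RNA classes. An FPKM of 1 on a transcript of 1 kb corresponded to about 34.9 fragments in the eGFP library and 37.7 in the TLX library, and the depth of the TLX library was 1.08 times that of the eGFP library. Genes above 0 numbered 21816 and 24078, and genes with at least 1 FPKM numbered 13313 and 13736.

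NR2E1 (ENSG00000112333; chromosome 6, 108166058 to 108188809 in GRCh38, GENCODE 29) was listed at 0.668 FPKM in the eGFP library and 40.5 FPKM in the TLX library. The difference was 4.64 on the log2(FPKM + 1) scale and the ratio of the values was 60.7, with a 95% interval of 43.8 to 84.2 that covers counting error only. About 36.5 and 2391 fragments lay behind these values. None of the other measured members of the nuclear receptor family that includes TLX was at least 2-fold apart. NR2F6 was at 1.56 FPKM with eGFP and 2.21 with TLX, RXRA of chromosome 9 at 0.808 and 1.21, NR2C2 at 7.65 and 8.53, NR2F2 at 22.8 and 24.0, NR2C1 at 44.4 and 39.7, NR2F1 at 2.43 and 1.85, and RXRB at 8.15 and 5.87. With NR2E1 included, 5 of the 8 measured members were higher with TLX, and their median difference of 0.11 sat at percentile 63.5 of 10000 random lists of the same size matched on mean expression. The percentile describes these 2 libraries only.

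Most genes had similar levels in the libraries. Of 14335 genes with at least 1 FPKM in at least 1 library, 480 were at least 2-fold higher and 366 at least 2-fold lower in the TLX library on the log2(FPKM + 1) scale, which understates the difference of low genes. Among the 11599 protein-coding genes, 281 were higher and 182 lower by that measure, with a median difference of 0.06 and quartiles of -0.19 and 0.33. The correlation across genes was 0.93 (Pearson), and genes are not independent replicates. Of 6 common reference genes chosen after their values were seen, HPRT1 was at 49.7 and 52.6 FPKM with eGFP and TLX, ACTB at 943 and 1049, TBP at 9.05 and 10.4 and GAPDH at 342 and 414, while EEF1A1 (2298 and 1598) and B2M (975 and 576) were lower with TLX. Rescaling both libraries to the same sum moved the median of all genes from 0.05 to 0.21 and gave 587 higher and 251 lower genes, so the balance of higher to lower genes depends on the scaling. Rescaling to the same upper quartile gave 462 higher and 371 lower genes. Small RNA made up most of the summed FPKM, while sums of protein-coding genes were 359103 with eGFP and 350662 with TLX. Among examples picked after the values were seen, TRNAI6 (42641 FPKM with eGFP) and MT-RNR1 (32272) were listed at 0 with TLX. SCARNA22 was at 174266 and 98979, while SNORD3A, RN7SL1 and RN7SL2 were higher with TLX. Rescaling to the same sum rests partly on such values, and whether the zeros are sound was not tested. With a pseudocount of 5 the split was 106 higher and 122 lower.

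**Figure D1:**
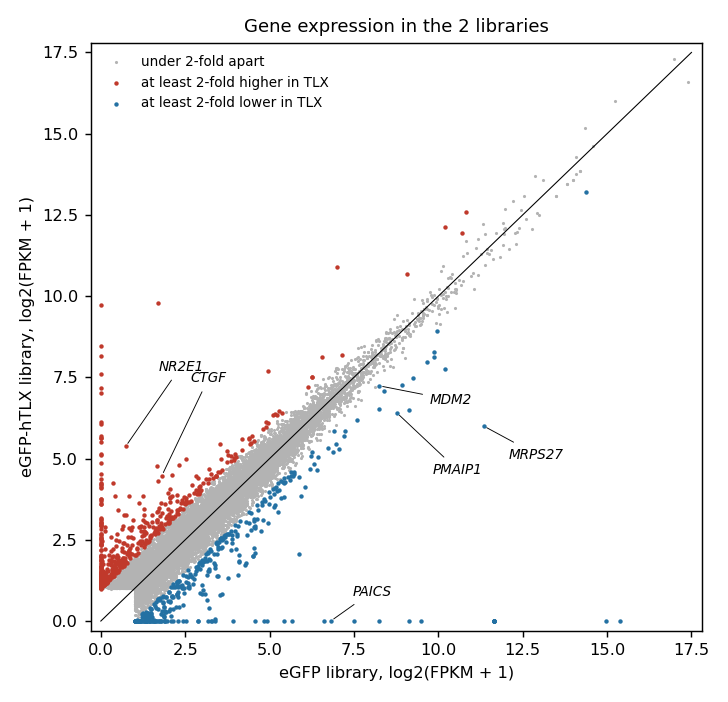
Each point is a gene past the low-value filter, with log2(FPKM + 1) in the eGFP library on the x axis and in the TLX library on the y axis, and the line marks equal values. Red points are the 480 genes at least 2-fold higher and blue points the 366 at least 2-fold lower in the TLX library, and points on either axis are genes listed at 0 in 1 library.

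NR2E1 was among the 10 genes furthest higher in the TLX library. Also higher were SFTA1P, a long noncoding RNA (0.273 and 17.99 FPKM with eGFP and TLX), HIST1H1T, a testis histone H1 gene (2.19 and 26.3), CITED1, a transcriptional coactivator (0.784 and 13.4), NAP1L2, a nucleosome assembly protein gene (0.411 and 9.68), and ZNF160, a zinc finger gene (0.0064 and 6.78). Lower were MRPS27, a mitochondrial ribosome gene (2594 and 63.1), RARRES1, a retinoic acid responsive gene (8.30 and 0.327), LRP1B, an LDL receptor relative (10.6 and 0.727), CHODL, a lectin-like membrane protein gene (15.9 and 1.65), CPS1, the first enzyme of the urea cycle (18.2 and 2.33), and SULT1A1, a sulfotransferase (18.6 and 2.45). The eGFP value of MRPS27 exceeded that of EEF1A1 (2298), and whether it is a sound estimate was not tested. The rest of the 10 largest differences in each direction involved an exact 0. ZNF888 (130 FPKM with TLX), NRP1 (17.1), HFM1 (7.08) and C5orf46 (6.60) were listed at 0 with eGFP, and MT-RNR1 (32272 FPKM with eGFP), PAICS (111), RMRPP4 (22.8) and LRLE1 (8.82) were listed at 0 with TLX. PAICS is a purine synthesis enzyme that dividing cells use, so a listed 0 is not read here as absence, and 126 and 83 of the 2-fold genes were listed at 0 in the eGFP and TLX library.

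A ranking restricted to protein-coding genes above 0 in both libraries was added after these zeros were seen. It placed the matricellular growth factor gene CTGF (2.496 and 21.2 FPKM with eGFP and TLX), the adhesion genes TENM1 (1.36 and 13.3) and PCDH19 (0.619 and 8.65), the protease inhibitor gene SLPI of chromosome 20 (0.588 and 6.61) and the tubulin gene TUBA4A (0.531 and 6.13) among the 15 furthest higher. Among the 15 furthest lower it placed the proapoptotic gene PMAIP1 of distal 18q (435 and 84.0), the mTOR inhibitor gene DDIT4 (22.3 and 3.77), the chemokine gene CXCL12 (7.47 and 0.786), the metalloprotease gene ADAMTS18 (6.96 and 0.787) and RAB28 (59.8 and 13.4). Of the 15 higher genes, 6 lay on chromosome X and 4 were zinc finger genes of chromosome 19, while 2 of the 15 lower genes lay on distal 18q.

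Genes reported elsewhere as repressed by TLX were mixed, and the 3 higher members were under 5 FPKM in both libraries. Lower in the TLX library were SMAD7, an inhibitor of TGF-beta signalling that adjoins a block of lower genes on distal 18q (12.3 and 6.45 FPKM with eGFP and TLX), CDKN1A, the p21 cell cycle inhibitor (51.3 and 34.3), HES1, a Notch effector (38.7 and 27.8), and NDRG2 (10.6 and 9.11). Higher were the water channel gene AQP4 (0.470 and 1.02), BMP4 (1.17 and 1.82) and the DNA demethylation enzyme gene TET3 (2.41 and 3.41). The list had 5 of 8 measured members lower and a median of -0.19, at percentile 7.65 of the matched random lists. With a filter of 5 FPKM its percentile was 0.36 and its median -0.46. Rescaled to the same sum its median was -0.03.

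Genes reported elsewhere as activated by TLX were also mixed. The angiogenic factor VEGFA (9.87 and 5.33 FPKM with eGFP and TLX), the stem cell factor SOX2 (5.32 and 2.78) and the metalloprotease MMP2 (12.8 and 8.01) were lower with TLX. EPAS1, a hypoxia-inducible factor (3.74 and 5.77), the cyclin gene CCND1 (5.61 and 7.79) and SIRT1 (27.3 and 29.9) were higher, and CDK4 was at 108 in both. The median of the 7 measured members was -0.00, at percentile 40.4, and its sign flips when the libraries are rescaled to the same sum. Among corepressor partners of TLX, RERE (27.7 and 46.8), RCOR1 (5.91 and 8.2), HDAC5 (1.56 and 2.21), HDAC7 (2.29 and 2.61), KDM1A (68.2 and 70.9) and HDAC2 (154 and 158) were higher. HDAC1 (77.1 and 72.6), HDAC3 (52.4 and 44.4) and BCL11A (7.04 and 5.54) were lower, and the list had a median of 0.06 at percentile 58.1. Rescaling to the same sum turned the direction of CDK4, HDAC1 and NR2C1, and centring on the median that of HDAC2.

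Of 50 gene lists fixed before the data were examined, 42 had at least 5 measured members. The medians of 11 lists lay above and of 5 below the central 95% of the matched random lists, where 2.1 are expected by chance. Lists share members, so these counts are not independent. The random lists were drawn gene by gene, so the 2.1 takes no account of members that vary together. The excess describes these libraries only.

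Epithelial genes and heat shock genes were the most clearly higher groups in the TLX library. Epithelial genes had a median of 0.89, above all 10000 random lists, with 8 of 9 measured members higher. They included the cell adhesion gene CDH1 (2.22 and 9.54 FPKM with eGFP and TLX) and the keratin genes KRT8 (34.9 and 82.5), KRT19 (6.62 and 16.7) and KRT18 (37.7 and 86.4). All 16 heat shock genes were higher, from HSPA8 (796 and 810) to HSPA1B (14.8 and 34.1), with a median of 0.63 that also lay above all random lists. HSPH1 was at 28.8 and 61.5 and the chaperone HSP90AA1 at 195 and 338. HSPA1A (20.4 and 42.7) and HSPA1B are near-identical copies, so the division of reads between them is uncertain.

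Genes of cholesterol synthesis and glycolysis were also higher, by smaller amounts. In cholesterol biosynthesis 17 of 20 measured genes were higher, with a median of 0.30 at percentile 99.8. They included MVD (0.471 and 2.27 FPKM), DHCR7 (2.74 and 5.94), EBP (33.9 and 54.3) and HSD17B7 (10.9 and 17.7). The median was 0.47 when rescaled to the same sum. In glycolysis 14 of 17 were higher, among them PFKL (1.87 and 3.32), ALDOC (1.24 and 2.201), GPI (81.3 and 116) and ENO1 (375 and 503), with a median of 0.27 at percentile 99.3. Matching the random lists on GC content and length as well put glycolysis at percentile 92.8, within the bounds.

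Signalling, differentiation and tumour suppressor lists also stood higher. Immediate-early genes had a median of 0.35 at percentile 97.8, with CTGF, CYR61 (2.94 and 9.97 FPKM with eGFP and TLX), KLF4 (1.78 and 4.21) and FOSL1 (0.497 and 1.51) furthest apart. Feedback genes of the MAPK pathway had a median of 0.47 at percentile 98.2, with ETV4 (0.0717 and 1.16), EPHA2 (1.26 and 3.25), ETV5 (1.99 and 4.31) and DUSP5 (3.96 and 7.68) higher. Targets of TGF-beta and BMP had a median of 0.36 at percentile 98.8, with CTGF, TGFBI (0.923 and 4.87) and ID1 (0.581 and 2.07) higher and SMAD7 lower. Neuronal genes had a median of 0.43 at percentile 98.1, with TUBB3 (0.382 and 3.12), INA (3.74 and 12.04) and NEFH (0.259 and 2.05) higher and SNAP25 (2.12 and 0.785) lower. Pluripotency genes had a median of 0.60 at percentile 98.2 over 5 members, with KLF4, LIN28B (15.9 and 25.8) and DNMT3B (2.33 and 4.04) higher and SOX2 lower. Tumour suppressors had a median of 0.23 at percentile 97.6, with CDH1, CDKN2B (6.93 and 12.2) and APC (14.7 and 22.04) higher. KLF4 and CDKN2B lie on chromosome 9 and ID1, DNMT3B and SNAP25 on chromosome 20, where most genes were higher. A filter of 5 FPKM turned the medians of the MAPK and TGF-beta lists negative, to -0.08 and -0.26, and every list of this group fell within the bounds under at least 1 alternative. A pseudocount of 5 put the medians at 0.20 for immediate-early, 0.16 for MAPK, 0.14 for TGF-beta, 0.24 for neuronal and 0.30 for pluripotency genes, and rescaling to the same sum put that of tumour suppressors at 0.40.

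Small noncoding RNA of ribonucleoprotein complexes had a median of 0.37 at percentile 99.8, with 10 of 13 higher, but at 96.9, within the bounds, when the random lists were matched on GC content and length too. RN7SL1, the RNA of the signal recognition particle, was at 38171 and 66268 FPKM with eGFP and TLX, RNU12 of the minor spliceosome at 30.2 and 205, and SCARNA2 at 6.09 and 11.3. FPKM of such short transcripts depends strongly on the length model.

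**Figure D2:**
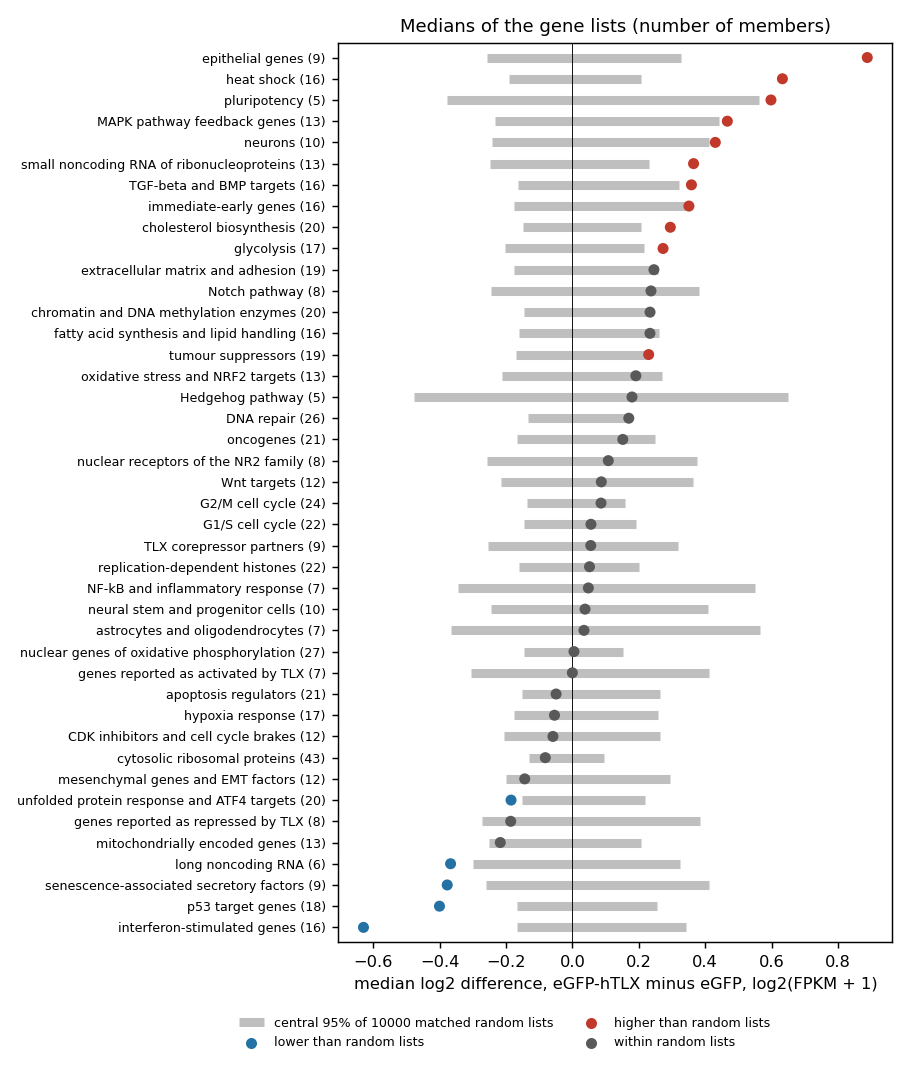
Points are the medians of the 42 tested gene lists, as the log2(FPKM + 1) difference of the TLX minus the eGFP library, with the number of measured members in parentheses, and gray bars span the central 95% of 10000 random lists matched on expression. Red points lie above and blue points below the bars, led by epithelial genes at 0.89 and interferon-stimulated genes at -0.63.

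Interferon-stimulated genes were the most clearly lower group. Of 16 measured members 13 were lower in the TLX library and 7 at least 2-fold lower, with a median of -0.63 below all 10000 random lists. IFI44L was at 4.42 and 0.411 FPKM with eGFP and TLX, IRF9, a subunit of the interferon-activated transcription complex, at 15.2 and 3.67, IFIT1 at 26.9 and 7.65, and IFI44 at 2.56 and 0.127. The RNA sensor gene IFIH1 was higher (4.35 and 7.48). The size of the median depended on the processing, at -0.19 (percentile 0.18) when rescaled to the same sum, -0.28 with a pseudocount of 5, -0.23 without a filter and -1.12 with a filter of 5 FPKM. Of 25 genes in the list, 9 did not reach 1 FPKM in either library.

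The list of p53 target genes was lower as well. Of 18 measured members 14 were lower, with a median of -0.40 below all random lists. They included MDM2, a ubiquitin ligase gene (303 and 150 FPKM), BTG2 (38.7 and 19.6), TP53INP1 (12.7 and 6.49) and the growth arrest gene GADD45A (21.1 and 12.3). With list means in place of medians the percentile was 2.76, just within the bounds, and rescaling to the same sum gave a median of -0.23.

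The unfolded protein response and ATF4 list was lower with members on both sides. Of 20 measured members 12 were lower, with a median of -0.18 at percentile 0.98. Rescaled to the same sum its median was -0.01, at percentile 1.33, so it was then low only relative to the random lists, and a pseudocount of 5 put it at 2.86, within the bounds. Genes of amino acid supply and stress, DDIT4, SLC7A11 (7.83 and 1.69 FPKM with eGFP and TLX), ASNS (150 and 56.5) and PHGDH (46.3 and 24.1), were lower along with ATF4 (404 and 223), while the endoplasmic reticulum chaperone HSPA5, on chromosome 9, was higher (22.3 and 46.1). Secretory factors of senescent cells had a median of -0.38 at percentile 0.37, with CXCL12, IGFBP5 (6.97 and 2.65), VEGFA and IGFBP7 (68.0 and 46.2) lower. The sign of that median flips without a filter, and also when mitochondrial, small and short RNA are left out before rescaling. Long noncoding RNA had a median of -0.37 at percentile 0.89, with NEAT1 (26.5 and 11.0), GAS5 (194 and 134), MALAT1 (287 and 202) and TUG1 (66.9 and 57.0) lower, and a median of -0.19 when rescaled to the same sum. Without a low-value filter the last 2 lists were at percentiles 29.6 and 30.7.

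Cell cycle lists lay within the random lists. G1/S genes had a median of 0.06 at percentile 66.7, with CCNE2 (20.4 and 13.6 FPKM with eGFP and TLX) and RRM2 (92.9 and 67.0) lower and UHRF1 (9.09 and 12.1) higher. G2/M genes had a median of 0.09 at percentile 84.9, with the proliferation marker MKI67 (29.9 and 59.6), CDC20 (42.8 and 70.2) and AURKA (41.3 and 65.4), the last on chromosome 20, higher. CDK inhibitors had a median of -0.06 at percentile 23.3, DNA repair genes 0.17 at 97.3, oncogenes 0.15 at 85.7, apoptosis regulators -0.05 at 16.8 and replication-dependent histones 0.05 at 62.7. DNA repair genes passed the upper bound under 4 alternatives, such as percentile 98.7 without distal 18q and chromosomes 9 and 20. Without these regions the CDK inhibitor median was -0.18, at percentile 7.75. The signs of the CDK inhibitor, apoptosis and histone medians flip under at least 1 rescaling or centring.

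Metabolic and organelle lists were likewise within the bounds. Hypoxia genes had a median of -0.05 at percentile 20.035, oxidative stress genes 0.19 at 91.4 and fatty acid genes 0.23 at 95.7, with PLIN2 of chromosome 9 (12.3 and 22.2 FPKM) and ACLY (36.8 and 61.3) higher. Nuclear genes of oxidative phosphorylation had a median of 0.00 at percentile 53.1, cytosolic ribosomal protein genes -0.08 at 17.3 and mitochondrially encoded genes -0.22 at 5.01, or 2.335 and so below the bound among protein-coding genes only. The oxidative stress median was 0.12 without distal 18q and chromosomes 9 and 20. The signs of the hypoxia, oxidative phosphorylation and ribosomal protein medians flip under at least 1 rescaling or centring. The 3 measured metallothionein genes were higher, with MT1F at 13.1 and 25.7.

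Other signalling and lineage lists did not stand apart. The median was 0.05 for NF-kB genes (percentile 39.3), 0.09 for Wnt targets (53.4), 0.24 for the Notch pathway (86.7) and 0.18 for the Hedgehog pathway (59.6). It was 0.25 for extracellular matrix genes (96.7), -0.14 for mesenchymal genes (6.39), 0.23 for chromatin and DNA methylation enzymes (97.0), 0.04 for neural stem cell genes (38.8) and 0.03 for astrocyte and oligodendrocyte genes (35.8). Single members were far apart, such as the matrix genes COL12A1 (2.94 and 14.4 FPKM with eGFP and TLX) and TNC (5.51 and 17.3), the Wnt antagonist DKK1 (0.886 and 6.5), the neural factors SOX11 (0.0060 and 2.64) and PAX6 (32.4 and 17.6), and the mesenchymal factor ZEB1 (31.5 and 13.2). TNC lies on chromosome 9, where most genes were higher. With a filter of 5 FPKM the neural stem cell list stood lower, with a median of -0.64 at percentile 0.34. Rescaling to the same sum put the matrix list at percentile 98.3 and the chromatin list at 97.62, above the bound, and a pseudocount of 5 put the mesenchymal list at 2.35, below it. Without distal 18q and chromosomes 9 and 20 the Notch median was 0.03 (percentile 47.3) and the matrix median 0.16 (91.1). The signs of the NF-kB, neural stem cell and astrocyte medians flip under at least 1 rescaling or centring.

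Markers of other cell types were low in both libraries. No marker of leukocytes, erythroid, endothelial or adrenal cells or hepatocytes reached 1 FPKM in either library, and the highest was at 0.896. Among fibroblast markers only LUM reached it, at 14.6 and 19.9 FPKM with eGFP and TLX. Among kidney epithelium markers LRP2 (2.62 and 4.85), LHX1 (1.33 and 1.83) and WT1 (2.84 and 2.38) did.

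The differences were not spread evenly over the genome, which was examined after the gene values were seen. Among protein-coding genes past the filter and above 0 in both libraries, all 69 genes of distal 18q were lower in the TLX library, from DYM to PARD6G (chromosome 18, 49041474 to 80247546, GRCh38). Their median was -1.18, with quartiles of -1.43 and -0.88, a median ratio of 0.367, and 45 genes at least 2-fold lower. They included DYM (39.3 and 12.8 FPKM with eGFP and TLX), the TGF-beta mediator SMAD4 (78.3 and 27.4), the transcription factor TCF4 (29.9 and 7.07) and PMAIP1. The other 121 genes of chromosome 18 had a median of -0.06 and 1 gene at least 2-fold lower, and SMAD7 lies just proximal to the segment, whose edge was drawn after the values were seen.

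On chromosome 9, 91.8% of 473 genes were higher in the TLX library, with a median of 0.49 and a median ratio of 1.499. On chromosome 20, 83.9% of 286 genes were higher, with a median of 0.39 and a ratio of 1.37. The median was 0.05 over the 10188 genes of the autosomes other than 9, 18 and 20. Zinc finger genes named ZNF on chromosome 19 included 1 cluster where 10 of 24 between 52 and 54 Mb were at least 2-fold higher and the median was 0.49. The window was drawn after the values were seen, and 5 of the 173 elsewhere on the chromosome, with a median of -0.10, were also at least 2-fold higher. In that cluster ZNF28 was at 1.18 and 11.5 FPKM, ZNF468 at 1.42 and 8.64 and ZNF677 at 0.692 and 8.66. Zinc finger genes of a cluster are related in sequence, so reads can be divided among them.

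**Figure D3:**
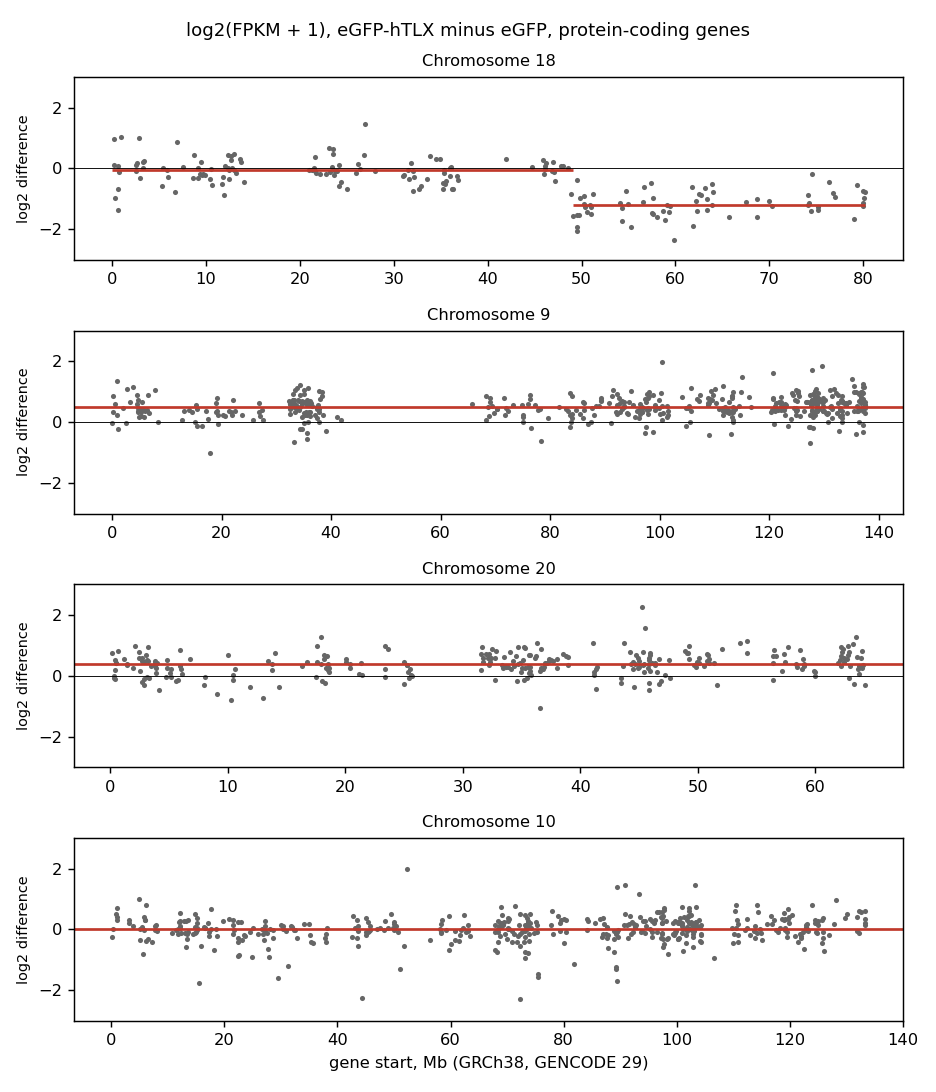
Points are protein-coding genes past the filter and above 0 in both libraries, placed by gene start in GRCh38 on the x axis in Mb, with the log2(FPKM + 1) difference of the TLX minus the eGFP library on the y axis and red lines at medians. Distal 18q lies at a median of -1.18 and chromosomes 9 and 20 at 0.49 and 0.39, while chromosome 10, drawn for comparison, lies at 0.02.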

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

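Tests on genes above 0 in both libraries, on protein-coding genes only, without distal 18q and chromosomes 9 and 20, and with GC content and length matching were chosen only after the result was seen. No paired analysis was possible because each group has 1 library. The alternative that keeps genes by estimate status and confidence interval was not run, since the files used here give none, and the locus under 300 bases was replaced by the longest GENCODE 29 transcript under 300 bases. The count of 846 genes at least 2-fold apart became 1644 with a pseudocount of 0.1 and 228 with a pseudocount of 5. It was 446 with a filter of 5 FPKM and 463 among protein-coding genes only. Leaving out mitochondrial, small and short RNA and then rescaling gave 1672, with 16421 genes past the filter in place of 14335. The count was 2709 at 1.5-fold and 153 at 4-fold, and between 637 and 846 under the others. The difference of NR2E1 was 5.73 with a pseudocount of 0.1 and 3.01 with a pseudocount of 5. Of 1022 values of 205 genes of the naming rule, 4 took another direction, at 0.18 for CDK4, 0.09 for HDAC1 and 0.02 for NR2C1 when rescaled to the same sum and -0.02 for HDAC2 when centred on the median. Pseudocounts cannot turn a direction. Lists standing apart numbered 16, became 10 with list means (8 of them among the 16), and 12 to 17 otherwise. Epithelial, heat shock, cholesterol and interferon lists stood apart under all alternatives run. Of 219 values for the 16 lists, 184 kept the call, 33 lost it and 2 moved to the other side of the random median, and the cause was not tested. Those 2 came with a filter of 5 FPKM, at percentile 26.6 for MAPK feedback, within the bounds, and 2.4 for TGF-beta and BMP targets, past the opposite bound, and that filter gave 96.2 for glycolysis, 88.1 for neurons and 96.6 for tumour suppressors. List means gave percentiles of 2.76 for p53 targets, 95.5 for glycolysis, 91.7 for MAPK feedback, 97.0 for TGF-beta, 96.7 for neurons, 84.9 for pluripotency, 96.3 for tumour suppressors and 3.37 for long noncoding RNA. A pseudocount of 5 gave 2.86 for the unfolded protein response, 92.3 for MAPK feedback, 90.5 for TGF-beta and 96.4 for pluripotency, and a pseudocount of 0.1 gave 95.7 for immediate-early genes and 97.2 for tumour suppressors. No filter gave 29.6 for senescence factors, 97.3 for immediate-early genes, 90.3 for pluripotency and 30.7 for long noncoding RNA. Leaving out mitochondrial, small and short RNA and then rescaling gave 35.3 for senescence factors, 97.495 for tumour suppressors and 5.88 for long noncoding RNA. Rescaling to the same sum gave 95.4 for MAPK feedback. GC content and length matching gave 92.8 for glycolysis, 97.1 for immediate-early genes, 92.3 for tumour suppressors and 96.9 for small noncoding RNA. Protein-coding genes only gave 96.7 for immediate-early genes, genes above 0 in both gave 97.4 for tumour suppressors, and leaving out the 3 regions gave 97.2 for immediate-early genes and 93.1 for tumour suppressors. Among the other lists 15 of 358 values passed the bounds. Depth limits the low genes, since 1 FPKM on 1 kb rests on about 34.9 and 37.7 fragments.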

Other observations

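The tests of GC content and length and of scaling for the chromosomal regions, and the analyses without these regions or with GC content and length matching for the gene lists, and the count of p53 list members in these regions, were chosen only after the result was seen. Of 5 second gene lists, written after the first lists were seen and before their own values were, 4 stood apart. The amino acid response list, with tRNA synthetases and genes of serine and one-carbon metabolism, had 20 of 27 measured members lower in the TLX library and a median of -0.34, below all 10000 random lists. MTHFD2 was at 185 and 96.2 FPKM with eGFP and TLX, STC2 at 6.003 and 3.23, and NUPR1 at 1.71 and 0.112.

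Chaperones outside the first heat shock list were higher in 18 of 23 cases, with a median of 0.33 at percentile 99.97. HSPB8 was at 12.3 and 36.7 FPKM, FKBP4 at 74.1 and 134, and the chaperonin gene TCP1 at 208 and 342. Epithelial junction genes and targets of the YAP coactivator were higher in 16 of 19 cases, with a median of 0.41 at percentile 99.96. ANKRD1 was at 17.0 and 48.1, AMOTL2 at 1.14 and 4.23, and the tight junction gene TJP1 at 23.5 and 42.1.

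The 69 genes of distal 18q were lower and the genes of chromosomes 9 and 20 higher, and copy number was weighed as an explanation of both. Scaling or depth is argued against for distal 18q by its median, which lay -0.95 from the lowest median of 69 consecutive genes elsewhere (-0.23). The segment was picked for its low values, so only the size of that gap bears on scaling, not its sign. GC content and transcript length are argued against by percentiles of 0 for distal 18q and 100 for chromosomes 9 and 20 among lists matched on them. The regions were picked for their values, which favours extreme percentiles, although the same matching moved chromosome 19 from percentile 100 to 83.0. Noncoding genes and pseudogenes, not used to find the pattern, were at percentile 99.92 on chromosomes 9 and 20 together, as a higher copy number predicts, but at 99.94 on chromosome 9 and only 79.9 on chromosome 20 alone, and their medians were 0.09 for 48 processed pseudogenes and 0.23 for 76 others. On distal 18q a lower copy number predicted a percentile below 2.5 and the 7 such genes were at 53.3, so that prediction failed. The 7 genes include 3 pseudogenes at 0.03 to 1.05, whose reads may come from related genes elsewhere. Of the other 4 genes 3 were lower (median -0.75), so these few genes cannot exclude a lower copy number. What set distal 18q apart stays open, and with 1 library per group an effect of TLX cannot be told from a difference between clones or cultures.

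Interferon-stimulated genes were lower, and a candidate explanation is lower interferon signalling in the cells of the TLX library. A second list with no member of the first was at percentile 0.16, with a median of -0.18 and 24 of 34 members lower, such as IFITM3 (3.96 and 1.33 FPKM) and HLA-B (90.9 and 64.1). Position on distal 18q, chromosome 9 or chromosome 20 is argued against by a percentile of 0 without these regions, where 1 of 16 measured members lies, and GC content and transcript length by a percentile of 0 with lists matched on them. Whether TLX or another difference between the cultures lay behind it was not tested.

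Targets of p53 were lower, and lower p53 activity in the cells of the TLX library was weighed as an explanation. A second list of p53 targets was at percentile 10.76, with a median of -0.08 and 14 of 22 members lower, so the prediction written beforehand, a percentile below 2.5, was not met. After the value was seen, that bound was judged too strict to exclude a lower activity, since targets need not all move and members went both ways, with CCNG1 (381 and 230 FPKM) and POLH (15.2 and 7.53) lower, TNFRSF10D (11.03 and 15.5) higher, and TRIM32 (6.36 and 9.33), on chromosome 9 where most genes were higher, also higher, so the explanation stays open. Position on distal 18q, chromosome 9 or chromosome 20 is argued against by the first list, of which 0 of 18 measured members lie there, and GC content and transcript length by a percentile of 0.01 with lists matched on them.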
